A study of Mus musculus with 11 samples.

How the data were processed

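Total RNA of terminal ileum from 8 SKG and 3 BALBc mice, each a separate animal per the labels, was amplified and hybridised to 1-colour Illumina bead arrays. Groups, replicate numbers and batches were taken from the sample descriptions. Each sample file holds, per probe, the mean bead signal, a detection value and the number of beads. The signal is an intensity that the authors exported without normalisation from GenomeStudio 1.9.0, per the file headers. The detection column is a fraction, equal to 1 minus the detection p against negative control beads, and is deposited as such. Bead numbers were deposited too and were used only as a check. The authors' deposited table of log2 values holds 5045 probes, and the series matrix holds the same rows and values. These are the probes with detection above 0.95 on all 11 arrays under the deposited names. GenomeStudio and limma are named in the submitters' processing notes, with no version or role for limma. The scale of that table matches log2 (within batch 3, its differences between arrays had rank correlations of 0.873 to 0.973 with those of log2 signal), but its centring is not given in the sources used here. Its column medians were 0.0932, 0.165 and 0.354 for SKG replicates 1 to 3. They were 0.0476, 0.0488, 0.0196, 0.0703 and 0.0457 for SKG replicates 4 to 8, and 0.186, 0.152 and 0.00801 for BALBc replicates 1 to 3. Between batches 2 and 3 its differences had rank correlations of 0.217 to 0.51 with those of log2 signal. For pairs of batch 1 with another batch the range was −0.557 to 0.622. The table therefore served as an alternative only, fitted with batch 1 under the deposited names.

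In the 3 files of batch 1 the rows were out of step with the probe list. Bead numbers, which are set when a chip is made, correlated at 0.0057 with those of the other 8 arrays, against 0.549 between 3 and 5 of those other arrays. The mean log signal of batch 1 was aligned to that of the other arrays by a banded forward-backward alignment in row order. Its settings were an assumed correlation of 0.85, a gap penalty of 3, a band of 400 rows, a lowest match score of −4, a posterior probability of at least 0.99 and stretches of at least 20 rows with 1 shift. Bead numbers played no part in the alignment. It placed 20194 rows in 157 stretches, with shifts of up to 164 rows, and the bead number correlation of the placed rows was 0.567. With the 3 BALBc arrays alone as the reference, 93.8% of these rows were placed on the same row, and with the 5 SKG arrays of batch 3 alone 98.6%. The alignment was tested on simulated row orders made from 3 SKG arrays of batch 3 with 250 blocks moved. There it placed 67.2% of rows, and 99.7% of those on their true row. Some arrays of the simulated reference shared the batch of the moved arrays, which is not so for batch 1. The share on the true row may therefore be too high for the real rows. The choice to realign was made before any test between the strains was run. The last version of the alignment, and the decision to test probes without a placed row on 8 arrays, were settled after first counts of calls had been seen. The version was picked on the simulated rows, out of several tried. Results without batch 1 and with rows as deposited are given as alternatives chosen after seeing the data. Ranges over the alternatives include both, although with rows as deposited the batch 1 values do not follow the probe names.

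Signals were background-corrected with the normexp model from detection p, given an offset of 16, quantile normalised and put on the log2 scale (neqc in limma 3.58.1, R 4.3.3, statmod 1.5.0). Background correction and quantile normalisation preceded realignment, since they do not use row order across arrays. The alternative scalings preceded it too, and cyclic loess compares arrays row by row. There batch 1 values were fitted against rows of other probes, so the cyclic loess results do not show scaling alone. Probes with a detection p under 0.05 on at least 3 arrays were kept: 14462 probes, 11701 of them on 11 arrays and 2761 on 8. SKG was compared with BALBc by limma over all 11 samples, with batch as a random block through a consensus correlation of 0.489, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Differences are SKG minus BALBc on the log2 scale, and group means are plain means of the normalised values. A fitted difference weighs the batches and so is not the difference of those means. A probe that was not above background on any array of a group has a bound only. The bound is the mean of the brighter group against, per array of the dimmer group, the higher of the probe's own value and the lowest value among probes above background. Probe names were matched to the gene table of assembly GRCm38.p6: of 18138 names, 14309 matched by symbol, 2885 by an older name, 73 had several matches and 871 none. Names without a match were kept as the files give them. The probe of Ly6m has an older clone name in the files and was named through this table. The assembly used for the probes is not given in the sources used here, so the table served for names, chromosomes and the order of neighbouring genes only.

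For gene lists, the kept probe with the highest mean stood for a gene. Lists were tested with camera (preset correlation 0.01, two-sided) on values whitened with the batch correlation, over the 8705 genes with values on all arrays, and adjusted over 37 lists. Camera was repeated with an estimated correlation, and fry was run beside it. A further list of sex chromosome genes was a check only. Counts of members in the text cover all measured members, including those on 8 arrays. They go by the fitted difference, which weighs the batches, so the plain group means of a gene can point the other way. Before the data were examined it was fixed that Zap70 and Runx3 would be named. So would the 10 largest rises and 10 largest falls among called genes with the same sign in batch 3, with 1 probe per gene and predicted genes last, up to 4 called members of each list by smallest p, and otherwise, for a list past camera, its 2 members with the smallest p. Of the genes this rule gives, 1 is not reported here. Other alternatives, also fixed then, were batch as a fixed block (which rests the strain difference on batch 3 and its 1 BALBc animal), no batch term, batch 3 only, the replicate number as a block, other background corrections and scalings, the authors' table, no filter or a stricter one, a trended and robust variance prior, array weights, and leaving out each sample. Leaving out batch 2 was added after seeing the data.

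The tests were tested on simulated data. On 11701 probes with the estimated variances and a within-batch correlation as estimated, limma with batch as a random block recovered 41.8% of 2-fold, 89.6% of 4-fold and 100% of 8-fold changes in a comparison of 8 with 3 samples. Of its calls 7.78% were false, against 5.43% with batch as a fixed block and 17.6% with no batch term. The correlation was estimated at 0.331, below the 0.489 simulated. With no list changed camera passed 0 of 37 lists of independent genes. Members of real lists are correlated (estimated at 0.22 for T cell receptor signalling and 0.722 for smooth muscle). The simulation therefore cannot give the false rate of camera at its preset correlation of 0.01 on these data. Replicate arrays of 1 batch and strain had squared differences of 4.55 to 34 times the squared bead error, so no pair looked like the same sample deposited again.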

Results

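RNA from the terminal ileum of 11 naive mice aged 8 to 12 weeks was hybridised to Illumina MouseRef-8 expression bead arrays, with 1 array per mouse. The SKG strain (8 mice) has a BALB/c background and carries a point mutation in Zap70, a kinase of T cell receptor signalling, that weakens the signal. The control group was 3 BALB/c mice. The arrays came in 3 batches. Batch 1 held SKG replicates 1 to 3, batch 2 held BALBc replicates 1 and 2, and batch 3 held SKG replicates 4 to 8 with BALBc replicate 3, so batch 3 alone contained both strains. Each array measured 25697 probes, of which 12400 to 14081 gave a signal above background at a detection p under 0.05. The number of arrays, and in particular the 3 BALBc animals, limits the precision of every value. Median raw signals were 187.5 and 163.0 in batch 2 and lay between 92.9 and 109.3 on the other 9 arrays. SKG replicate 6 stood apart from the other SKG animals of batch 3: squared differences between its array and theirs were 23.7 to 34 times the squared bead error, against 4.61 to 7.21 among the others.

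The signals of the 3 batch 1 arrays did not follow the probe names of their rows. Their rank correlation with the arrays of batches 2 and 3 was 0.0768 to 0.0966 across probes, while it was 0.861 to 0.896 among the batch 1 arrays and 0.838 to 0.947 among the other 8. The rows of batch 1 were therefore realigned to the probe list. Of the rows, 20194 (78.6%) were placed, and their rank correlation with the other arrays was then 0.828 to 0.884. A high signal correlation follows from placing rows by signal and is no check. Bead numbers, which played no part in the placing, correlated with those of the other arrays at 0.00568 before and 0.567 after it. Probes without a placed batch 1 row were compared on the 8 arrays of batches 2 and 3. Those 8 arrays needed no realignment, and the counts of calls from them alone stand beside the counts from all arrays.

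**Figure D1:**
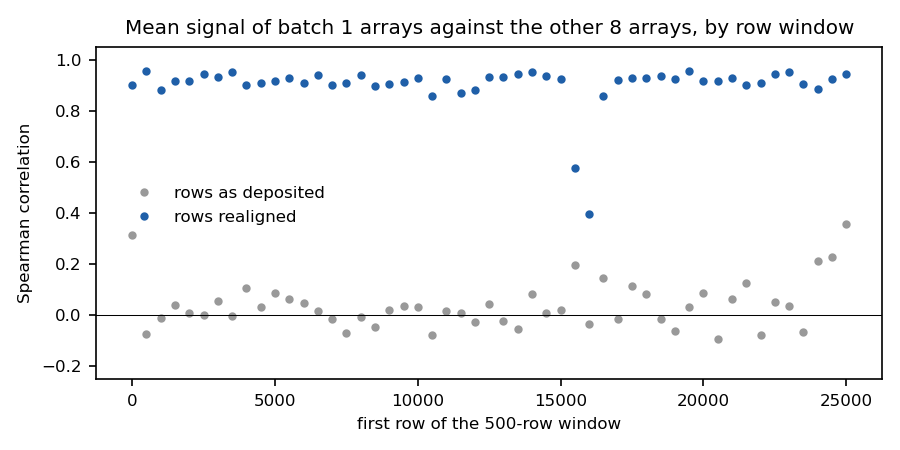
Spearman correlation, across the probes of each 500-row window, between the mean signal of the 3 batch 1 arrays and the mean signal of the other 8 arrays, against the first row of the window. Grey points are rows as deposited and blue points realigned rows; realigning moved most windows from near 0 to about 0.9, with 2 windows staying lower. The rows were placed by this signal, so the rise is built in.

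The first question was whether the gene that carries the SKG mutation, and Runx3, a transcription factor of the CD8 T cell lineage that the series names, differed in transcript level. The brighter Zap70 probe gave a normalised log2 signal of 5.73 ± 0.53 (SD, n = 5) in SKG and 6.87 ± 0.59 (SD, n = 3) in BALBc. All 5 SKG values (4.89, 6.17, 6.13, 5.57 and 5.91 for replicates 4 to 8) lay below the 3 BALBc values (6.54, 6.52 and 7.55). The log2 difference of −1.52 (SE 0.39) did not pass (limma adjusted p = 0.095). A second Zap70 probe differed by −1.41 (adjusted p = 0.157), and the third was not above background on any array. Batch 1 values of the Zap70 probes could not be placed. Within batch 3 the difference of the brighter probe was −1.82. The single Runx3 probe was not above background on any of the 11 arrays (lowest detection p 0.317), so no Runx3 level could be compared. The Zap70 call depended on the samples: without SKG replicate 6 its adjusted p was 0.0406, and it passed in 4 of 26 alternative settings (adjusted p 0.0153 to 0.543). These 4 include batch 1 rows as deposited, where batch 1 values do not follow the probe names. They also include array weights, a setting that called 4493 probes higher and 3111 lower, so neither is evidence for Zap70. Another is cyclic loess, which was run before batch 1 rows were realigned, so it is no clear evidence either.

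The second question was which transcripts differed between the SKG and BALBc ileum. Several genes known from T cells were among those lower in SKG. Itgae, the integrin chain that holds intraepithelial lymphocytes to the epithelium, fell by 3.15 on the log2 scale (SE 0.38), from 9.36 ± 0.27 (SD, n = 3) in BALBc to 6.08 ± 0.68 (SD, n = 8) in SKG, and its other 4 kept probes went the same way. Of these the brightest passed too (−2.85, SE 0.26, adjusted p = 7.49e-05). Ccl5, a chemokine of cytotoxic T cells, fell by 3.07 (SE 0.65). The T cell surface receptor Cd6 fell by 2.80 (SE 0.45) and was called with all 3 of its kept probes. Cd8b1, the beta chain of the CD8 co-receptor, fell by 2.57 (SE 0.50). The largest fall was that of Aoc3, an amine oxidase of vessels and adipose tissue also known as vascular adhesion protein, at −4.68 (SE 0.32), with 5.43 ± 0.37 (SD, n = 8) in SKG against 9.88 ± 0.57 (SD, n = 3) in BALBc. Among transcripts higher in SKG, Ly6m, a member of the Ly6 family, differed most, at 5.36 (SE 0.55), with 11.64 ± 0.54 (SD, n = 5) against 7.20 ± 1.46 (SD, n = 3). The limma adjusted p was 0.00131 for Itgae, 0.0416 for Ccl5, 0.0109 for Cd6, 0.0305 for Cd8b1, 7.51e-06 for Aoc3 and 0.00131 for Ly6m. With batch as a fixed block, which rests on the 1 BALBc animal of batch 3, Ccl5 did not pass (adjusted p = 0.135, in a range over its alternatives of 3.55e-05 to 0.206). Without that animal, BALBc replicate 3, Cd8b1 differed by −1.24, Cd6 by −1.95 and Ccl5 by −3.29, none past the threshold. Ly6m differed by 3.62 without it and still passed. With the replicate number as a block Ly6m differed by 3.12 and did not pass (adjusted p = 0.122, in a range over its alternatives of 4.59e-09 to 0.122). Cd6 was above background on 4 of the 8 SKG arrays, and its value ran from −3.31 to −1.26 over the alternatives.

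In all, 80 probes (75 genes) were higher and 60 probes (51 genes) lower in SKG at a limma adjusted p under 0.05, among 14462 probes tested. On the 8 arrays of batches 2 and 3 the counts were 45 and 36, and 60 probes were called in both fits. Each of the 140 called probes had the same sign in batch 3 alone, which is part of the fit, so this is no independent check. In 136 of them (97.1%) the SKG and BALBc values did not overlap, against 1.21% by chance for a probe not picked for its difference. These probes were picked for it, so the share describes them and tests nothing. Cd8b1 was among those that overlapped, since SKG replicate 6 (6.544) lay above BALBc replicate 1. The other large falls were those of Ceacam10 (−3.37, SE 0.49), Arl2bp (−2.77, SE 0.19), Vat1 (−2.77, SE 0.44), Gtf2ird2 (−2.76, SE 0.25) and Ifi35 (−2.62, SE 0.30). Ceacam10, Arl2bp and Gtf2ird2 were above background on 1 of the 8 SKG arrays and on all 3 BALBc arrays. The size of their falls therefore depended on the background floor, and so did their rank: without background correction they differed by −1.53, −1.05 and −1.05, and over all alternatives by −4.70 to −1.53, −2.86 to −1.05 and −2.92 to −1.05. The other large rises were those of Epha1, an ephrin receptor (2.57, SE 0.37), Pigt (2.11, SE 0.39) and Arl6ip5 (2.05, SE 0.36). They were followed by Sumo3 (1.98, SE 0.28), Usp12 (1.93, SE 0.30), Gprc5a (3.74-fold, log2 SE 0.40), the endoplasmic reticulum chaperone gene Pdia3 (1.87, SE 0.40) and BC025446 (1.87, SE 0.21). Ly6m, Arl6ip5, BC025446 and Vat1 were measured on 8 arrays. With batch as a fixed block Pigt, Arl6ip5, Usp12, Gprc5a and Pdia3 did not pass (adjusted p = 0.105, 0.0834, 0.0677, 0.0901 and 0.0672). Their ranges over all alternatives were 8.8e-07 to 0.19, 3.36e-07 to 0.189, 1.05e-07 to 0.175, 3.74e-05 to 0.298 and 3.69e-05 to 0.296. Lat, Jchain, Gbp2 and Ly6c1, named below, missed the threshold there too. When BALBc replicate 3 was left out Vat1 differed by −1.29, Pdia3 by 1.17 and Gprc5a by 2.16, none past the threshold.

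The counts depended on single animals and on the scaling. Without SKG replicate 6 there were 484 higher and 287 lower probes, and without BALBc replicate 3, which leaves no batch with both strains, 480 and 1038. Without SKG replicate 2 there were 125 and 88. Leaving out SKG replicate 3 gave 41 and 34, replicate 4 gave 36 and 36, replicate 5 gave 38 and 40, replicate 7 gave 31 and 30 and replicate 8 gave 43 and 36. Leaving out BALBc replicate 1 gave 38 and 28, and BALBc replicate 2 gave 20 and 23. Quantile normalisation gave 57.1% of the calls as higher, scaling to the 75th percentile 76.4% (139 higher, 43 lower) and cyclic loess 25.7% (19 higher, 55 lower). Cyclic loess was run before batch 1 rows were realigned, so its share does not show scaling alone. The median log2 difference of all tested probes was 0.0258 under quantile normalisation and 0.251 under 75th percentile scaling. Aoc3, Arl2bp and the brightest Itgae probe (−2.85) passed in every alternative in which they were tested (26, 24 and 27 alternatives). The Itgae probe with the difference of −3.15 passed in 25 of 27 (adjusted p 1.17e-06 to 0.0564). Of 11 fits without 1 animal, Ccl5 and Cd8b1 each missed the threshold in 7, Lat and Arl6ip5 in 6, Jchain in 4, Vat1 and Cldn4 in 3, Cd6 and Pigt in 1, Gbp2 and Pdia3 in 9, and Cela1, Gprc5a and Ly6c1 in 8.

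**Figure D2:**
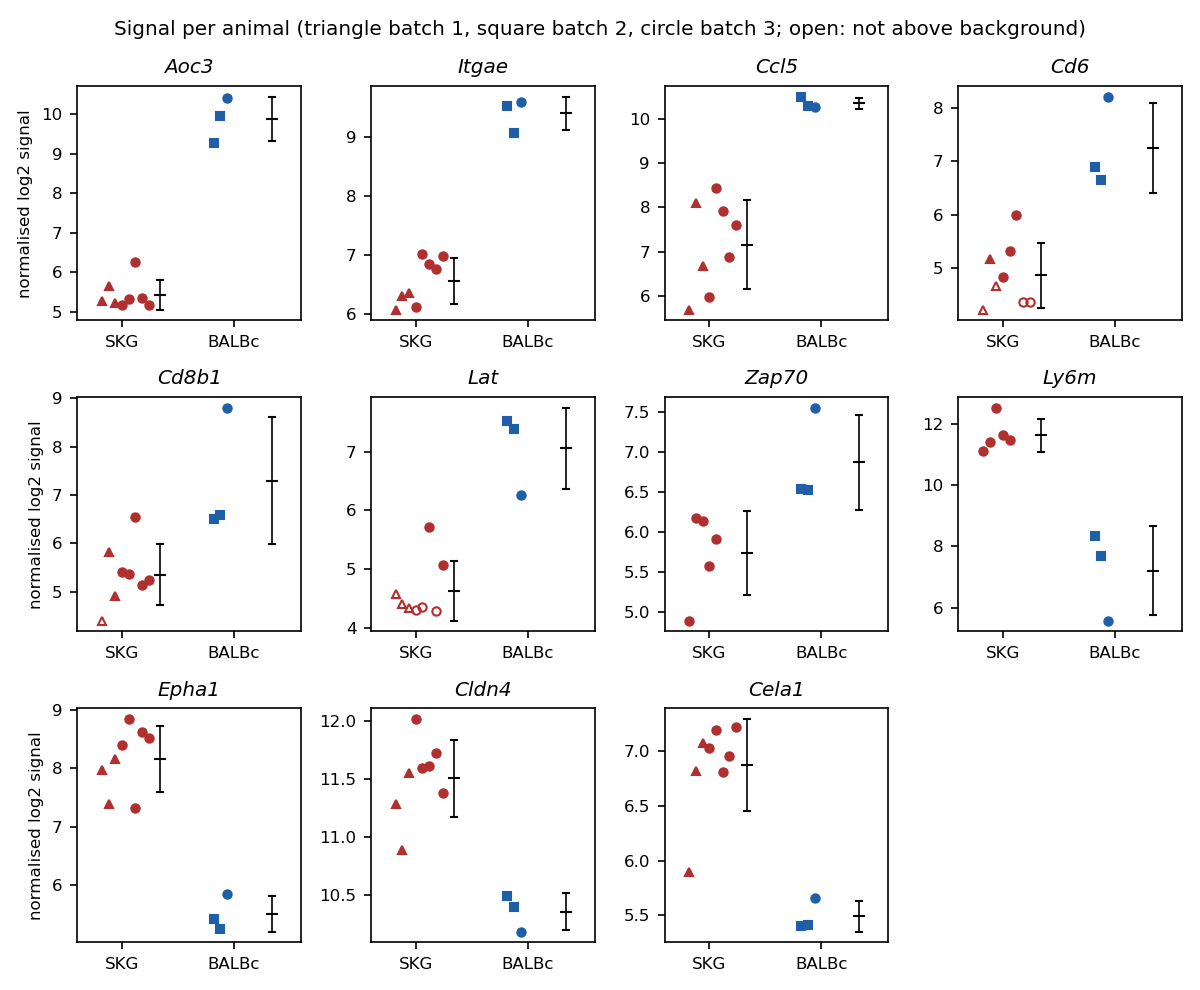
Normalised log2 signal of 11 named genes in each animal, SKG in red and BALBc in blue, with triangles for batch 1, squares for batch 2 and circles for batch 3. Open symbols were not above background, and bars give the mean and SD of each strain. Aoc3 was 5.43 on average in SKG and 9.88 in BALBc. Batch 1 has no placed value for Zap70 and Ly6m.

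The genes were then grouped by lists fixed before the data were examined. Members are counted as higher or lower by the fitted difference, which weighs the batches, and the count by plain group means is given where it is another. The T cell receptor signalling list had the smallest camera p: all 18 measured members were lower in SKG (17 by plain means), with a median log2 difference of −1.15 over all samples (−1.13 with genes not above background at their bound) and −1.52 within batch 3. Of these, 5 passed over all genes tested and 14 when adjusted over the list alone. They included Cd6, Lat (−2.01, SE 0.39, and −2.86 to −0.73 over the alternatives), an adaptor of the T cell receptor complex above background on 2 of the 8 SKG arrays, and its partner Lcp2, which was not above background on any SKG array and was at least 2.30-fold lower. Tcf7, a transcription factor of naive T cells, was likewise not above background in SKG and at least 1.63-fold lower, by 1 probe. Its second kept probe differed by −0.43 (adjusted p = 0.322). Lcp2, Tcf7, Trat1 and Fyn were kept through the BALBc arrays alone, so the filter largely fixed their direction. The bounds of Lcp2 and Tcf7 hold for plain means of the quantile normalised values, which ignore the batches. Within batch 3 Lcp2 differed by −0.849 and Tcf7 by −0.824 on the log2 scale, with SKG values below background, so these are not bounds. The BALBc animal of batch 3 had 5.18 for Lcp2 and 5.28 for Tcf7. The lowest values above background on the SKG arrays of that batch were 4.73 to 4.89. Neither the 2.30-fold nor the 1.63-fold bound held there. Lcp2 passed in 12 of 20 alternatives (log2 difference −1.94 to −0.371) and Tcf7 in 13 of 21 (−1.12 to −0.248), and both calls were lost with batch as a fixed block, 75th percentile scaling and cyclic loess. In the CD8 and intraepithelial lymphocyte list all 14 members were lower (median −0.80, and −1.11 within batch 3). Cxcr3 among them was likewise kept through the BALBc arrays alone. Itgae, Cd8b1 and Ccl5 passed over all genes, 9 passed when adjusted over the list alone, and 11 did not pass over all genes. Both lists were shifted against the other genes in camera with a preset correlation (adjusted p = 1.82e-13 and 1.09e-08). With an estimated correlation neither was (adjusted p = 0.119 and 0.143). Against zero, fry gave adjusted p = 0.00506 and 0.011. The Runx family and CD4/CD8 lineage factor list was lower too (7 of 9 members, median −0.39, and −0.47 within batch 3, 2 lower when adjusted over the list alone, camera adjusted p = 0.0175, adjusted p = 0.143 with an estimated correlation), with no member past the threshold. No Runx gene was among the 9 measured members, so the list says nothing of Runx levels. Its smallest p-values were those of Tgfbr2 (−0.92, SE 0.23) and Satb1 (−1.43, SE 0.48). With BALBc replicate 3 left out Satb1 differed by −0.225, and the list means were −0.82 (T cell receptor), −0.90 (CD8) and −0.25 (Runx family), against −1.30, −1.20 and −0.43 with all samples. The first 2 still passed. The Runx family list did not then pass (adjusted p = 0.421, the highest over its alternatives, the lowest being 0.00754).

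Lists of antigen presentation and of other leukocytes were also lower. For MHC class II presentation 11 of 12 members were lower (median −1.44, and −1.27 within batch 3). None passed over all genes and 6 passed when adjusted over the list alone. H2-Aa, a class II chain, differed by −2.74 (SE 0.63, adjusted p = 0.0544), and Ciita, the class II transactivator, by −1.62 (SE 0.52, adjusted p = 0.148). For macrophages, dendritic cells and granulocytes 17 of 19 members were lower (median −0.685, and −0.945 within batch 3, 4 lower when adjusted over the list alone), with Adgre1 at −1.58 (SE 0.37) and Ms4a7 at −0.98 (SE 0.24), neither past the threshold. In the plasma cell list 11 of 14 members were lower (10 by plain means, median −0.26, and −0.33 within batch 3). When adjusted over the list alone 4 were lower and 1 higher. Jchain, the joining chain of secreted IgA and IgM, fell by 2.13 (SE 0.41, and −3.39 to −0.90 over the alternatives) and was the 1 member that passed. It was above background on 4 of the 8 SKG arrays. The interferon response list (19 of 33 members lower, median −0.30) had 2 members that passed, Ifi35 and Gbp2 (−1.23, SE 0.24), and its median within batch 3 was −0.09. When adjusted over the list alone 11 of its members were lower and 2 higher. With batch as a fixed block, where the strain difference rests on the 1 BALBc animal of batch 3, this list and the plasma cell list did not pass (camera adjusted p = 0.431 and 0.0767, with ranges over all alternatives of 0.00185 to 0.578 and 0.012 to 0.816). The Peyer patch and germinal centre list had 14 of 16 members lower (10 by plain means, median −0.28, and −0.43 within batch 3, 5 lower and 1 higher when adjusted over the list alone), with Ccl19 at −1.40 (SE 0.39) and Serpinb6b at −1.07 (SE 0.31), neither past the threshold. The camera adjusted p of these 5 lists was 2.01e-05, 0.000257, 0.03, 0.0379 and 0.044. With an estimated correlation none was shifted (adjusted p = 0.214, 0.143, 0.143, 0.578 and 0.493). Without BALBc replicate 3 the Peyer patch list had a mean of −0.002 (−0.52 with all samples) and did not pass, nor did the plasma cell list, while the other 3 passed, the interferon list with a mean of −0.654 (−0.424 with all samples). Leaving out 1 animal ended the Peyer patch call in 6 of 11 fits. Among the genes, leaving out BALBc replicate 3 gave values far from those above: Ccl19 differed by 0.07, Serpinb6b by −2.19, Adgre1 by −3.05, H2-Aa by −4.64 and Jchain by −3.39.

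Higher in SKG were 4 lists of absorptive epithelium and exocrine tissue. For enterocyte lipid uptake 15 of 18 members were higher (16 by plain means, median 0.45, and 0.40 within batch 3), and the smallest p-values were those of the fatty acid transporter gene Slc27a4 (1.08, SE 0.30) and the cholesterol transporter gene Npc1l1 (1.00, SE 0.28), neither past the threshold over all genes. For bile acid and FXR genes 11 of 12 were higher (10 by plain means, median 0.39, and 0.54 within batch 3), with Abcc2 at 1.64 (SE 0.39) and Cyp27a1 at 1.08 (SE 0.31), neither past the threshold. Of the jejunum markers 7 of 9 were higher (median 0.78, and 0.93 within batch 3), with Apoa4 at 1.61 (SE 0.57) and Rbp2 at 1.56 (SE 0.41), again short of the threshold. Of the 21 pancreatic acinar genes on the array only 8 were kept, among them Zg16, which is also on the goblet cell list. All 8 were higher (7 by plain means, median 0.535, and 0.681 within batch 3), though Ctrl (0.03) and Zg16 (0.02) hardly differed. Ctrb1 was kept through SKG arrays alone, so the filter largely fixed its direction. Cela1, an elastase, rose by 1.38 (SE 0.28). The camera adjusted p was 7.44e-05, 0.00474, 0.031 and 0.00257 for the 4 lists. With an estimated correlation none was shifted (adjusted p = 0.214, 0.193, 0.322 and 0.143). When adjusted over the list alone 2, 3, 1 and 3 members were higher. Cldn4, a tight junction gene, rose by 1.29 (SE 0.24), while the tight junction list as a whole did not pass (adjusted p = 0.361). Of these 4 lists lipid uptake alone passed without BALBc replicate 3. The values of Rbp2 and Cyp27a1 were then 2.85 and 1.97, and Cela1 (1.42) and Cldn4 (1.02) did not pass. Cela1 also missed the threshold with batch as a fixed block (adjusted p = 0.107, in a range of 3.92e-06 to 0.208).

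Lists of stroma, blood and dividing cells were lower in SKG. In the cell cycle list 26 of 30 members were lower (23 by plain means, median −0.54, and −0.40 within batch 3), with Mcm5 at −1.06 (SE 0.25) and Plk1 at −0.89 (SE 0.24), neither past the threshold over all genes. In the crypt stem cell list 14 of 16 were lower (13 by plain means, median −0.26, and −0.38 within batch 3), with Ephb2 at −0.71 (SE 0.18) and Tnfrsf19 at −0.85 (SE 0.30), neither past the threshold. The fibroblast and matrix list (20 of 21 lower, 14 by plain means, median −0.65), the endothelium list (17 of 18, 14 by plain means, −0.48) and the smooth muscle list (16 of 18, 9 by plain means, −0.41) had no member past the threshold, and their medians within batch 3 were −0.954, −0.669 and −0.809. Their smallest p-values were those of Dpt (−1.04, SE 0.26), Fbn1 (−1.44, SE 0.42), Emcn (−0.79, SE 0.25), Ramp2 (−1.11, SE 0.33), Flna (−1.20, SE 0.39) and Synm (−1.08, SE 0.39). All 6 members of the blood list were lower (5 by plain means, median −0.798, and −0.749 within batch 3). Its 1 member that passed was Ly6c1 (−1.52, SE 0.31), which is an antigen of endothelium and leukocytes and not of red cells. Of 29 ribosomal protein genes 20 were lower (19 by plain means, median −0.20, and −0.22 within batch 3, Rpl29 −0.83, SE 0.27, and Rpl30 −0.73, SE 0.30, neither past the threshold). The mean of the ribosomal list turned from −0.19 to 0.29 under 75th percentile scaling. The camera adjusted p of the cell cycle, crypt stem, fibroblast, endothelium, smooth muscle, blood and ribosomal lists was 2.01e-05, 0.0144, 2.83e-05, 0.00364, 0.0175, 0.0148 and 0.0263. With an estimated correlation none was shifted (adjusted p = 0.143, 0.325, 0.271, 0.462, 0.663, 0.271 and 0.578). In the same order 4, 1, 1, 0, 0, 2 and 0 members were lower when adjusted over the list alone. None of the 7 lists passed without BALBc replicate 3. The smooth muscle mean was then 0.22, endothelium −0.05 and fibroblast −0.24, against −0.425, −0.46 and −0.675 with all samples. Gene values depended on that animal too: without it Mcm5 differed by −0.34, Plk1 by −0.10, Tnfrsf19 by −0.18, Flna by −0.48, Fbn1 by −0.64 and Emcn by −0.435. Those of Dpt (−1.60), Rpl29 (−1.73) and Rpl30 (−1.62) were larger without it.

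**Figure D3:**
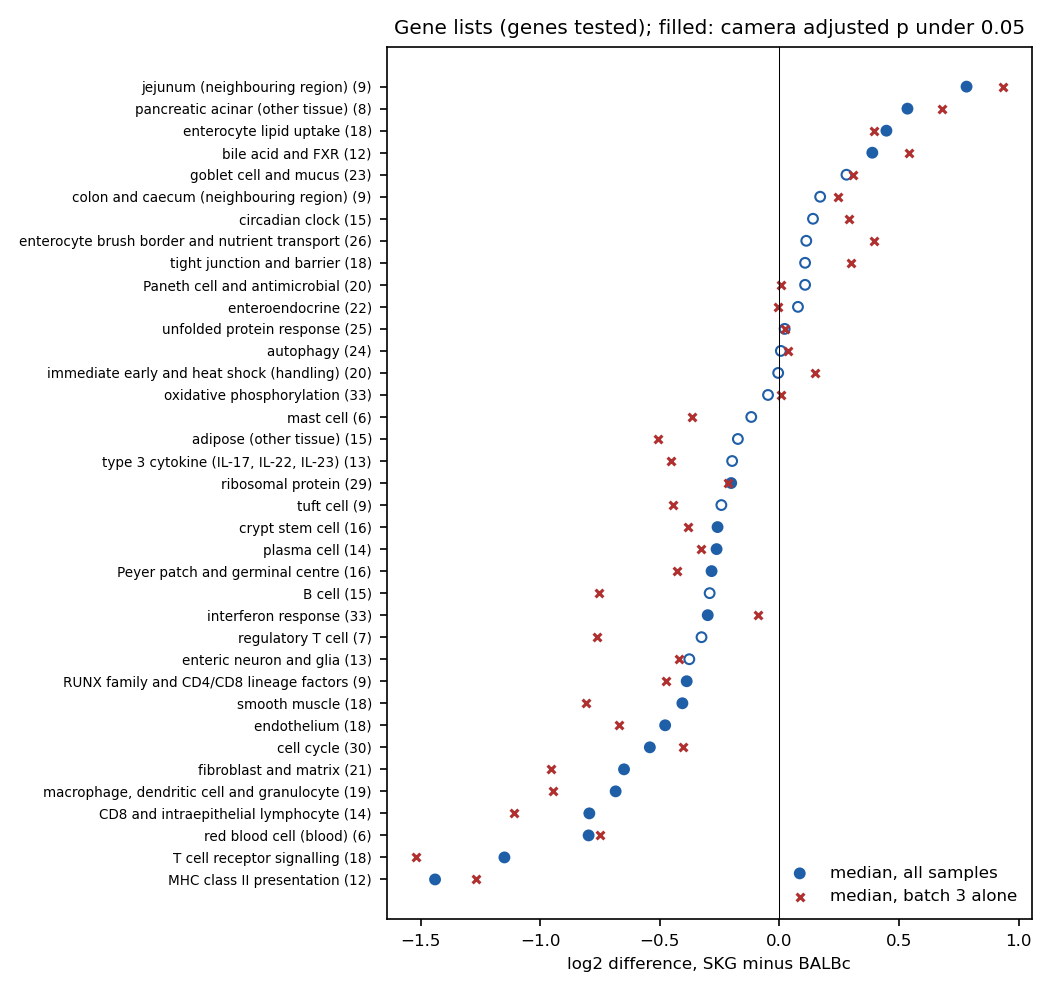
Median log2 difference between SKG and BALBc of the measured members of each gene list, over all samples (circles) and within batch 3 alone (crosses), with the number of members in parentheses. Filled circles mark the 19 of 37 lists that passed camera with a preset correlation, 15 lower and 4 higher. The T cell receptor signalling list had a median of −1.15.

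In camera 19 of the 37 lists tested passed, and 19 passed on the 8 arrays of batches 2 and 3. Without BALBc replicate 3 there were 7, and with an estimated correlation 0. The remaining 18 lists, among them those for goblet cells, Paneth cells, regulatory T cells and interleukin-17 cytokines, did not pass.

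Batches were compared within 1 strain to size the batch difference. A batch 1 row placed wrongly would differ in all 3 of its animals at once, so the counts may include such errors. Between the 3 SKG animals of batch 1, with realigned rows, and the 5 of batch 3, limma called 551 probes higher and 386 lower in batch 1 among 11701 tested. Without SKG replicate 1 the total was 230, without replicate 2 it was 465, without replicate 7 it was 607, and with rows as deposited it was 16640.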

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

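The tests of the row order in batch 1, of chance placement along chromosomes and of the T cell lists were chosen after the results had been seen. The other tests here were fixed beforehand.

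Among 75 results checked for an animal far from the other SKG animals, 6 stood out, where chance alone would give about 1 in 20. SKG replicate 1 had the lowest Pigt (9.17, next 10.27) and the lowest Cela1 (5.90, next 6.81). SKG replicate 2 had the highest Ceacam10 (6.04, next 4.40) and the highest Ramp2 (9.13, next 8.00). SKG replicate 8 had the highest Arl2bp (4.81, next 4.51), and SKG replicate 6 the highest Aoc3 (6.26, next 5.66).

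The signals of the 3 batch 1 arrays did not follow the probe names of their rows. Poor RNA or a failed hybridisation would leave bead numbers in place, but their correlation with the other arrays was 0.00568 under the deposited names, which argues against it. Rows shifted against the probe list are a candidate explanation: after realigning on signal alone the bead numbers correlated at 0.567. Where in the handling of the files the shift arose stays open. The authors' deposited table was filtered on the same rows.

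The T cell receptor and CD8 lists were lower in SKG. The 30 T cell and CD8 genes had a mean log2 difference of −1.10 and 117 genes of other non-epithelial lists one of −0.351 (exact permutation p of the difference = 0.00606, two-sided, the smallest that 165 splits allow). The T cell lists were picked for their shift, and the permutations did not keep the batches apart. MHC class II genes (fitted mean −1.51) were not among the 117. The test therefore does not decide whether less non-epithelial tissue in the SKG samples was the whole cause. Peyer patch tissue in the BALBc samples is left undecided in the same way: 23 B cell and Peyer patch genes had −0.14, and the difference had an exact permutation p of 0.00606. Within batch 3, with its 1 BALBc animal, that difference was −0.644, and the B cell list was itself lower there (median −0.753), while without that animal its mean was 0.47. A difference of the batch 2 arrays cannot be told apart from strain for the BALBc animals it holds, and within batch 3 the median difference of −1.23 rests on 1 BALBc animal. The strain difference itself stays open and untested.

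Several large falls involve genes that are neighbours on a chromosome: Aoc3, Ifi35 and Vat1 form a run with Ptges3l, which was higher, on chromosome 11 (order from GRCm38.p6). A candidate explanation is an inherited segment that differs between the colonies, but chance placement is not excluded: 28 of 120 called genes had another called gene within 10 measured genes, where random sets gave 14 to 36. On the 8 arrays of batches 2 and 3, whose rows were not moved, 20 of 67 did, above the 2 to 16 of random sets. That met the bound set beforehand against an error in the realigned rows, and rows that were not moved cannot carry one. The excess on the 8 arrays could not have come from such an error whatever the count, so it decides nothing about the realigned rows. Aoc3, Ifi35 and Vat1 were called there too (limma adjusted p = 0.000584, 0.00673 and 0.0179). The fit with realigned rows had no excess, so for that fit the test decided nothing. Sequence variants under single probes stay open: for 69.0% of the called genes with another kept probe (29 of 42, exact binomial 95% interval 52.9% to 82.4%) another probe went the same way. The bound fixed beforehand was 67%. That the whole interval must lie above it was settled after the value had been seen. By the point estimate alone this explanation would have been called excluded, for these 42 genes only. Aoc3, Ifi35 and Vat1 had no other kept probe, so no value of this share could exclude variants under their probes.

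Other ways of splitting the samples were counted. Over the 11701 probes with values on all arrays the strains gave 153 called probes, and 3 of 100 splits into 8 and 3 gave as many, the real one included. The highest of the others gave 552 probes, with SKG replicate 6 beside BALBc replicates 1 and 2, and the next gave 388, with SKG replicate 6 beside BALBc replicates 2 and 3. Both hold SKG replicate 6, which points to a structure of the samples in which that animal stands apart. With batch as a fixed block the strains gave 38 higher and 43 lower probes. For gene lists, 3 of 100 splits gave as many as the 19 of the real split, and the highest other also gave 19. Many lists also passed in splits that did not separate the strains: 16 with SKG replicates 1, 3 and 4 as the group of 3. For SKG batch 1 against batch 3, 1 of 56 splits, the real one, gave as many as its 937 probes, and the highest other gave 11. In each case the share of splits is under 0.05, the bound fixed beforehand. For the strains, other splits gave more probes or as many lists, so a chance split is not excluded. For SKG batch 1 against batch 3 the real split stood alone, which argues against a chance split. The splits into 8 and 3 did not keep the batches apart, so they say nothing against a batch difference.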

How the results depend on the processing

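Batch 1 rows as deposited, leaving out batch 1 and leaving out batch 2 were alternatives chosen after seeing the data. The others were fixed beforehand. With all samples there were 80 higher and 60 lower probes, 19 gene lists, a Zap70 difference of −1.52 and 937 probes between SKG batches. Counts moved by over 1.5 times with batch as a fixed block (38 higher), no batch term (793 higher, 898 lower, 9 lists), batch 3 only (2 and 12) and array weights (4493 and 3111, 5 lists), which gave BALBc replicate 2 a weight of 6.51 and BALBc replicate 3 one of 0.127. They also moved without background correction (92 lower), with 75th percentile scaling (139 higher), cyclic loess (19 higher), no filter (189 and 127), the stricter filter (126 higher) and the authors' table (8 and 16, 9 lists, 624 between SKG batches). Without batch 1 there were 45 and 36, without batch 2 there were 2 and 11. Cyclic loess was run before batch 1 rows were realigned, and the authors' table was fitted with none realigned. Their counts therefore do not show the effect of processing alone. With batch 1 rows as deposited there were 177 lower probes and 16640 between SKG batches. Fry passed 10 lists and camera with an estimated correlation 0, with the smallest adjusted p at 0.119. Zap70 passed with cyclic loess (−1.80), array weights (−0.87) and rows as deposited (−1.82). Fewer samples or probes are part of some settings; otherwise the cause was not tested.

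Leaving out 1 animal gave 20 to 484 higher probes, 23 to 1038 lower probes, 7 to 20 lists, a Zap70 difference of −1.70 to −0.80 and 230 to 1233 probes between SKG batches. The 20 lists came without SKG replicate 6 or a batch 2 animal, and the 7 without BALBc replicate 3. The replicate number as a block gave 22 higher and 18 lower probes and 9 lists. The numbers do not pair the animals: deviations of the same-numbered animals correlated at 0.238, −0.0133 and −0.179.

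Of the 140 probes called with all samples, the 29 of named genes were followed, and these kept their sign in each alternative that measured them. Without batch 1, 21 of the 29 probes passed, with batch as a fixed block 15, and under no background correction 23. The fewest passed with the replicate block (5 of 29), batch 3 only (6 of 24), without batch 2 (5 of 24) and in the authors' table (4 of 12). Turned in direction were the ribosomal protein list with 75th percentile scaling (mean 0.29), the smooth muscle list without BALBc replicate 3 (range −0.57 to 0.22; its mean was also above 0 with the replicate block, 0.0418, and in the authors' table, 0.0547), and the Peyer patch list in the authors' table (mean −0.29, camera direction higher). The adipose list, which did not pass, was lower in batch 3 only (−0.66) and with rows as deposited (−0.59). Batch 1 rows were not realigned in the authors' table either. The size of a difference was uncertain for genes near background: Lcp2 ran from −1.94 to −0.371, Tcf7 from −1.12 to −0.248 and Lat from −2.86 to −0.726.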

Other observations

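No test in this part was chosen after its result was seen, but the ranges over all alternatives include settings chosen after seeing the data.

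Lists of secretory and other epithelial cell types did not pass. For goblet cells and mucus 18 of 23 members were higher in SKG (17 by plain group means, median 0.28, camera adjusted p = 0.0518). Paneth cell and antimicrobial genes split 13 higher to 7 lower (median 0.11, mean of the tested genes −0.05, adjusted p = 0.83), enteroendocrine genes 12 to 10 (0.08, 0.99) and tuft cell genes 2 to 7 (5 to 4 by plain means, median −0.24, mean of the tested genes 0.01, 0.99). Brush border and nutrient transport genes had a median of 0.11 (0.152). Tight junction genes also had a median of 0.11 (0.361). Colon and caecum markers had a median of 0.17 (0.828). With batch as a fixed block, which rests on the 1 BALBc animal of batch 3, the goblet cell (mean 0.32), brush border (0.39) and tight junction (0.40) lists did pass as higher in SKG (adjusted p = 0.0424, 0.00134 and 0.00456, with ranges over all alternatives of 0.0226 to 0.641, 0.000271 to 0.991 and 0.00318 to 0.857). Without that animal the means were 0.143, −0.356 and −0.464, so the last 2 turned in direction.

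Lists of cell stress and energy metabolism did not pass. The unfolded protein response list had a median of 0.02 (adjusted p = 0.83), autophagy 0.01 (0.98), the immediate early and heat shock list, a sign of handling, −0.01 (0.99), the circadian clock 0.14 (0.213, and 0.0331 with batch as a fixed block, in a range of 0.0106 to 0.819, with a mean of −0.08 without the BALBc animal of batch 3) and oxidative phosphorylation −0.05 (0.304). Without BALBc replicate 3 the oxidative phosphorylation list passed as lower (mean −0.64, against −0.19 with all samples; adjusted p = 0.0356, in a range over all alternatives of 0.0356 to 0.947).

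Among lymphoid and stromal lists that did not pass, B cells had a median of −0.29 (adjusted p = 0.152; by plain group means 6 of 15 members were lower), regulatory T cells −0.33 (0.361), type 3 cytokine genes −0.20 (0.361), mast cells −0.12 (0.463), enteric neurons and glia −0.38 (0.0798) and adipose tissue −0.17 (0.99; 13 of 15 members were higher by plain means). With batch as a fixed block the B cell list passed (mean −0.76, adjusted p = 0.00955, with a range over all alternatives of 0.000379 to 0.87), a call that rests on the 1 BALBc animal of batch 3. Without it the mean was 0.47. For adipose tissue, tuft cells and Paneth cells camera pointed higher, against the median of the first 2 and the mean of the third. For the unfolded protein response, autophagy, handling and enteroendocrine lists camera pointed lower, with means of 0.0448, −0.016, 0.005 and −0.0151.

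The Y-linked probes of Eif2s3y, Kdm5d and 2 of the 3 for Ddx3y were not above background on any array with a value. The third Ddx3y probe was above background on all 11 arrays, a Uty probe on 6, and the Xist probes on 10 and 11.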
